A study of Mus musculus with 9 samples.

How the data were processed

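Stomach tissue of C57 mice, an inbred laboratory strain, was profiled 7 days after X-ray exposure of the stomach at 0, 6 or 12 Gy. Each of the 9 samples was hybridised to its own Agilent array carrying probes for messenger and long non-coding RNA, with 3 arrays per dose. The labels describe separate tissue samples, each from a mouse killed at that time, and group and replicate number were taken from the sample titles.

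Per the labels' protocols, total RNA was amplified into cRNA carrying a single dye, Cy3. Per the file headers and the submitters' processing notes, the arrays were read with Agilent Feature Extraction 10.7.1.1, which gave each spot a processed intensity, a raw mean and a local background median, all on a linear scale, together with flags for outliers, saturation and signal well above background. The deposited scanner values are therefore intensity before any normalization between arrays. The authors' deposited table of processed values holds log2 values. Set against the scanner values on the log2 scale, its columns correlated at 0.998 or above with slopes between 0.987 and 1.02, and each column had the same median of 3.99 and the same maximum of 18.2, as quantile normalization gives. The details of how that table was made are not given in the sources used here, and it served only as an alternative.

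Each array holds 148260 spots, of which 143286 are not controls, for 91188 distinct probes of 60 bases. The log2 processed intensity was taken relative to the 75th percentile of the non-control spots of the same array. A total of 183 outlier-flagged spot values were left out, and the spots of a probe were averaged. No spot was saturated. A probe was tested if it was well above background on all 3 arrays of at least 1 group, which left 32004 probes. A probe counted as well above background on an array when at least a share of 0.5 of its spots carried that flag. The 75th percentile of processed intensity ran from 49.0 to 76.7 across arrays, and between 31.6% and 39.9% of probes were well above background. The number of arrays limits the precision of every value.

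Probes were compared with limma 3.58.1 in R 4.3.3, with lmFit and eBayes over all 9 arrays, a mean per group and no covariate. The comparisons were 12 Gy against mock, 6 Gy against mock and 12 Gy against 6 Gy, with a moderated F test over the 3 groups, and p-values were adjusted by the Benjamini-Hochberg method at a threshold of 0.05. Single values such as the control probes were compared by two-sided exact permutation tests. Where a probe was not well above background on any array of a group, its fold is printed as at least a value. This sets the brighter group's mean against the dimmer group's mean of, per array, the higher of the probe's own signal and the lowest signal among probes well above background. It holds for this background correction only and leaves out the standard error, so it is not a bound across background corrections. Correlation of the changes at the 2 doses was set against simulations of unchanged groups sharing the mock arrays.

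The pipeline was tested on simulated data in which 200 of 32004 probes were changed by a known fold, with independent normal noise of each probe's own spread. For 12 Gy against mock it recovered 0% of 2-fold, 80.5% of 4-fold and 95% of 8-fold changes. For 6 Gy against mock the shares were 8.5%, 86% and 92%. These shares hold for that number of changed probes and for noise without co-variation between probes. The sensitivity in the real arrays may differ.

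The rule for single probes, fixed before the data were examined, took the probes past the threshold and, if there were none, the 5 with the smallest p in each direction, said not to have passed. The scanner files give each non-control probe its own identifier in place of a gene name and no genome position, and the reference tables used here do not pair these identifiers with genes. The planned gene lists and the planned separation of long non-coding from messenger RNA probes were therefore not analysed here, and only the first 2 probes in each direction are printed, with their sequences. The arrays lie on 3 slides, with scans following slides. Slide 1 holds mock replicate 1, slide 2 holds mock replicates 2 and 3 with 6 Gy replicates 1 and 2, and slide 3 holds 6 Gy replicate 3 with the 12 Gy arrays. Alternatives covered background correction, scaling, the authors' values, the filter on dim probes, the arrays in the fit, the replicate number and slide as blocks, the variance trend, array weights, the threshold and leaving out each array.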

Results

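Gene expression was measured in mouse stomach 7 days after mock treatment or X-ray exposure at 6 or 12 Gy, to profile the tissue during radiation-induced gastric injury. There were 3 arrays per dose, 9 in all. The share of probes well above background was 36.1% ± 4.21 in mock, 36.3% ± 3.42 at 6 Gy and 36.5% ± 0.467 at 12 Gy (SD, n = 3 each). The 75th percentile of the processed intensity was 60.7 ± 10.6, 64.4 ± 5.15 and 70.2 ± 6.83 in the same order (SD, n = 3 each; exact two-sided permutation p against mock of 0.7 at 6 Gy and 0.3 at 12 Gy).

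The only mouse genes that the files name are the control probes for Gapdh, a glycolytic enzyme, and Pgk1, another enzyme of the same pathway, each with a 3′ and a 5′ set. The Gapdh 5′ signal was 8.44 ± 0.15 in mock, 8.84 ± 0.12 at 6 Gy and 8.78 ± 0.36 at 12 Gy (log2 relative to the array's 75th percentile, SD, n = 3). By exact permutation, two-sided, the 6 Gy value differed from mock at p = 0.1 and the 12 Gy value at p = 0.2, where 0.1 is the smallest p that 3 against 3 arrays allow. The adjusted values were 0.667 and 0.6 by Benjamini-Hochberg over 8 control measures, so neither passed. Pgk1 3′ was 5.24 ± 0.36 in mock, 5.53 ± 0.15 at 6 Gy and 5.57 ± 0.30 at 12 Gy (SD, n = 3), differences within the spread between arrays. The difference between the 3′ and 5′ Gapdh sets, a measure of RNA integrity, was -1.41 ± 0.13 in mock, -1.62 ± 0.29 at 6 Gy and -1.61 ± 0.11 at 12 Gy (SD, n = 3). For Pgk1 the same difference was 1.70 ± 0.38 in mock, 1.88 ± 0.08 at 6 Gy and 1.96 ± 0.11 at 12 Gy, differences from mock of the opposite sign.

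The comparison of 12 Gy with mock asked which transcripts differed after the higher dose. The probe A_55_P2032081 (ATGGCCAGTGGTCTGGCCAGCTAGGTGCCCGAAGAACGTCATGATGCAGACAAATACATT) stood at 1.36 ± 0.42 in mock, 3.27 ± 0.29 at 6 Gy and 3.72 ± 0.40 at 12 Gy (SD, n = 3), a log2 difference of 2.36 with a standard error of 0.28. Its signal was above every mock array on each irradiated array. The probe A_55_P2085984 (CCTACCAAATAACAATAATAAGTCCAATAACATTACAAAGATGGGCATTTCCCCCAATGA) was at -0.01 ± 0.07 in mock, 0.70 ± 0.12 at 6 Gy and 1.16 ± 0.13 at 12 Gy. In the other direction, mmu_18118_PI428960544 (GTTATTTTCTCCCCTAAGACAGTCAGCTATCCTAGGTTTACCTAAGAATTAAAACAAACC) was well above background on the 3 mock arrays and on no irradiated array, at least 2.52-fold lower at 12 Gy. A_30_P01020619 (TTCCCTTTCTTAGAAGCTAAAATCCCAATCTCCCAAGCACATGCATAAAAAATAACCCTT) showed the same detection pattern and was at least 3.21-fold lower. These sizes depended strongly on the background correction and its offset. With normexp and an offset of 50, the log2 differences were -0.43 for mmu_18118_PI428960544, -0.54 for A_30_P01020619, 1.90 for A_55_P2032081 and 0.69 for A_55_P2085984. The 75th percentile of processed intensity ran from 49.0 to 76.7, so an offset of that size by itself shrinks differences of dim probes. Normexp without it was not run. The folds given as at least thus do not hold under that correction with its offset. None of these 4 probes passed the test: limma's Benjamini-Hochberg adjusted p was 0.128 for each.

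Across the 32004 tested probes, limma called 0 between 12 Gy and mock after Benjamini-Hochberg adjustment, and the smallest adjusted p was 0.128. At an unadjusted p under 0.05 there were 5660 probes, 17.7% of those tested, where chance alone gives 1600. Leaving out 12 Gy replicate 2 took this count to 3615, and the other arrays left out in turn gave 4209 to 7061. Of the 5660, 3811 were higher and 1849 lower at 12 Gy. The median probe was higher by 0.12 on the log2 scale, and the direction depended on the scaling: relative to the median of the probes detected on all arrays, 2163 were higher and 3007 lower, and after quantile normalization 2959 were higher and 2315 lower. In the authors' deposited values the split was 2620 higher and 2625 lower. The filter mattered too: without it 8515 of 91188 probes were at this level, 3874 higher and 4641 lower. The median difference was then -0.062. The 3 arrays of each group did not overlap for 7352 probes, 22.97%, against 10% on average by chance. Such averages leave out how widely the counts vary. In splits made after the results were seen, other divisions of these arrays gave 540 to 3587 probes at an unadjusted p under 0.05. With slide as a fixed block limma called 0 probes, with 3125 at an unadjusted p under 0.05. No slide held both mock and 12 Gy arrays, so the counts without that block do not set dose apart from slide. With the block, the difference summed 6 Gy against mock within slide 2 and 12 Gy against 6 Gy within slide 3. Slide 3 held only replicate 3 of the 6 Gy group, so the count of 3125 hangs on that array. The mock array alone on its slide did not enter the difference.

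The comparison of 6 Gy with mock asked the same of the lower dose. A_55_P2032081 again had the smallest p among the probes with higher signal, with a log2 difference of 1.91 ± 0.28 (SE). A_51_P473219 (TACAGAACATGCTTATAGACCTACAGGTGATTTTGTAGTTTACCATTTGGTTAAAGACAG) was at 0.44 ± 0.04 in mock and 1.43 ± 0.10 at 6 Gy (SD, n = 3). The probe mmu_16036_PI428960544 (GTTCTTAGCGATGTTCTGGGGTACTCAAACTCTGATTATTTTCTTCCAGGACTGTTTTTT) was well above background on every mock array and on no irradiated array, at least 2.80-fold lower at 6 Gy. A_55_P2375121 (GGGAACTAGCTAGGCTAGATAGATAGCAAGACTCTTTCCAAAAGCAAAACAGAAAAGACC) was at least 4.67-fold lower at 6 Gy, where no array had it well above background, and was detected on 2 of 3 arrays at 12 Gy. With normexp the log2 differences were -0.43 for mmu_16036_PI428960544, -0.77 for A_55_P2375121, 0.59 for A_51_P473219 and 1.48 for A_55_P2032081. The folds given as at least do not hold there either. For each of these 4 probes limma's Benjamini-Hochberg adjusted p was 0.189, which did not pass.

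**Figure D1:**
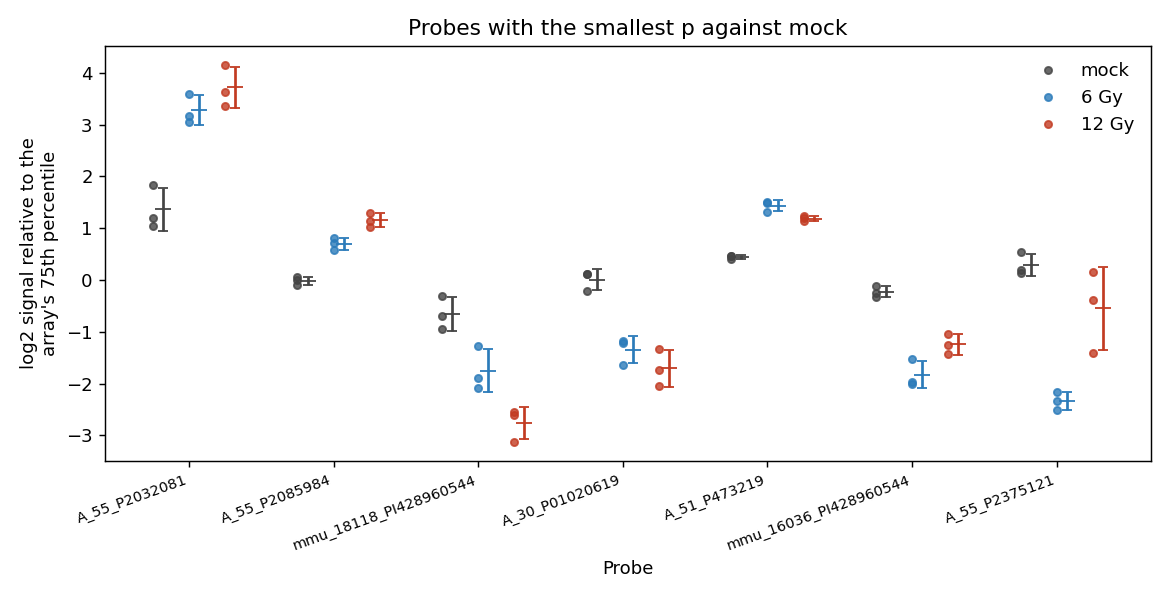
Signal of 7 probes on each of the 9 arrays, as log2 relative to the array's 75th percentile, with points for arrays and bars for the mean ± SD of 3 arrays in mock, 6 Gy and 12 Gy. A_55_P2032081 has a mean of 1.36 in mock and 3.72 at 12 Gy, and no probe passed the adjusted test.

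Over all probes limma called 0 between 6 Gy and mock after Benjamini-Hochberg adjustment, with a smallest adjusted p of 0.189. There were 5158 probes at an unadjusted p under 0.05, 3680 higher and 1478 lower, and 3562 to 6385 with 1 array left out in turn. The median probe was higher by 0.15 on the log2 scale, but this depended on the processing. It was 0.097 without mock replicate 1, 0.070 after quantile normalization and -0.036 without the filter on dim probes. Relative to the median of the probes detected on all arrays, 1294 were higher and 2731 lower, and after quantile normalization 2111 were higher and 1908 lower. In the authors' deposited values 1853 were higher and 2118 lower, and without the filter on dim probes 3244 were higher and 3917 lower. The groups did not overlap for 7450 probes, 23.28%, against 10% on average by chance. Other divisions of these arrays, made after the results were seen, gave 752 to 3135 probes at an unadjusted p under 0.05. Within slide 2, which held 2 arrays of each group, limma called 0 probes with 6525 at an unadjusted p under 0.05. With slide as a fixed block the differences equalled those within slide 2, so that fit adds no separate estimate. It called 0, with 6200 at that level.

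The comparison of 12 Gy with 6 Gy asked whether the doses differed from each other. The probe mmu_15982_PI428960544 (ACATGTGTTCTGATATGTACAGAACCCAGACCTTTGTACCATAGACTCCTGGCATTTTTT) was at -1.90 ± 0.27 at 6 Gy, with 1 of 3 arrays well above background, and -0.19 ± 0.24 at 12 Gy (SD, n = 3). The probe mmu_6645_PI428960544 (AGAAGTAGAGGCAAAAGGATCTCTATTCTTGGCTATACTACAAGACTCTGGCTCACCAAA) was at 0.96 ± 0.19 at 6 Gy and 1.98 ± 0.07 at 12 Gy. A_55_P1993263 (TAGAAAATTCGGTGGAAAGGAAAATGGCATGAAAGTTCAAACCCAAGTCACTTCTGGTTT) was at least 2.39-fold lower at 12 Gy, where no array had it well above background. The probe mmu_16072_PI428960544 (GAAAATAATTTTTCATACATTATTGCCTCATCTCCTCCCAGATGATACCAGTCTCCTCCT) was at 0.78 ± 0.01 at 6 Gy and -0.24 ± 0.25 at 12 Gy. With normexp the log2 differences of these 4 probes were 0.49, 0.72, -0.33 and -0.46, so the at-least fold of A_55_P1993263 does not hold there. Limma's Benjamini-Hochberg adjusted p was 1 for each. Over all probes limma called 0, with 1059 at an unadjusted p under 0.05, where chance gives 1600. This count depended on single arrays: it was 2608 without 6 Gy replicate 3, 468 without 6 Gy replicate 2 and 684 without 6 Gy replicate 1. Of the 1059, 449 were higher and 610 lower at 12 Gy. Relative to the median of the probes detected on all arrays the split was 554 higher and 479 lower. Within slide 3, with 3 arrays at 12 Gy and 1 at 6 Gy, limma called 0 probes with 789 at an unadjusted p under 0.05. With slide as a fixed block, whose differences equalled those within slide 3, the counts were 0 and 1055. As a random block they were 0 and 599.

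**Figure D2:**
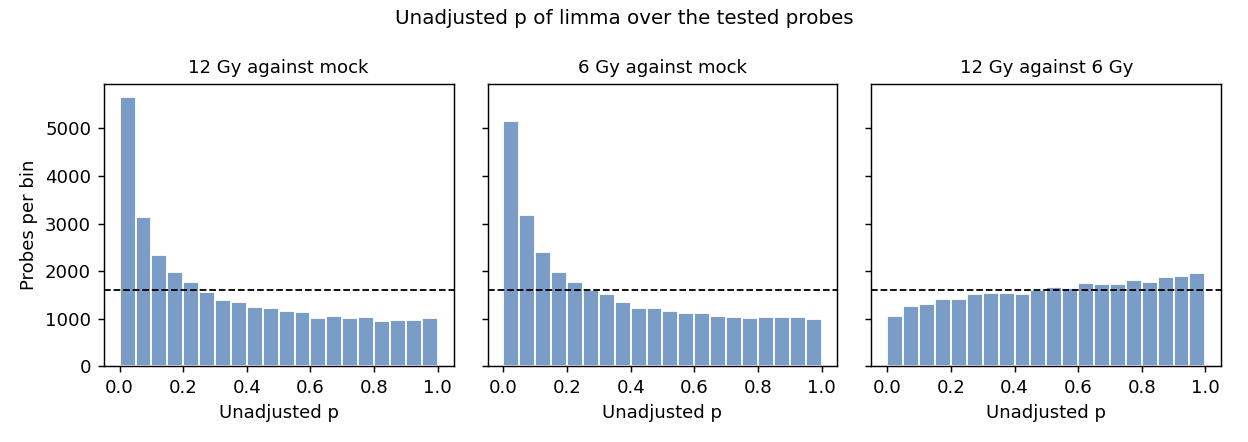
Histograms of limma's unadjusted p over 32004 probes in bins of 0.05, with the number of probes on the vertical axis and a dashed line at the even share of 1600 per bin. The first bin holds 5660 probes for 12 Gy against mock, 5158 for 6 Gy against mock and 1059 for 12 Gy against 6 Gy.

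Tested over the 3 groups together, limma's moderated F called 0 probes, with a smallest Benjamini-Hochberg adjusted p of 0.214 and 4571 probes at an unadjusted p under 0.05. The correlation of the log2 differences at the 2 doses was 0.804 across probes, where unchanged groups sharing these mock arrays gave 0.50. The covariance was 0.177 against 0.0597 in those simulations. Probes are not independent replicates. The simulations already held the shared mock arrays but no co-variation between probes, so part of the excess may still come from those arrays. In a check chosen after the results were seen, the mock arrays were divided 2 and 1 between the doses, so that none was shared. The 6 divisions gave correlations of 0.241 to 0.523 and covariances of 0.0769 to 0.136, each with 1 array as the only control of a dose. With no array shared, the 0.50 for shared controls is not the reference, since independent unchanged arrays then have an expected correlation of 0. This design was not simulated, and slide effects or co-variation between probes could move the value from 0. The covariance with shared controls exceeded its simulated value by 0.118. No simulation held a slide effect. 6 Gy replicate 3 shared slide 3 with every 12 Gy array, and without it the correlation was 0.622, where simulated unchanged groups in that design gave 0.447. With slide as a fixed block it was 0.773 against 0.655 in simulations of that design, with covariances of 0.229 and 0.179. Among probes at an unadjusted p under 0.05, 2173 were higher and 950 lower at both doses, where independent lists would share 438 and 85. Lists of the same sizes from simulated unchanged groups sharing the mock arrays had 1393 and 485 in common, on average over 100 simulations.

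Probes were also grouped by the prefix of their names, chosen after the values were seen. At 12 Gy, 16.7% of probes starting A_51 were higher and 1.83% lower at an unadjusted p under 0.05, and 13.7% of those starting A_55 were higher and 3.32% lower. Among probes starting mmu, 8.37% were higher and 10.5% lower, and among those starting A_30, 6.44% were higher and 8.42% lower. At 6 Gy the A_51 shares were 18.9% higher and 1.25% lower, the mmu shares 5.72% and 9.22%, and the A_30 shares 7.59% and 6.13%. After quantile normalization the A_51 shares at 12 Gy were 12.2% and 2.74%, and the mmu shares 6.92% and 12.0%. At 6 Gy quantile normalization lowered the A_51 share to 10.3% higher, with 1.69% lower, and turned the balance of A_30 to 4.88% higher and 8.17% lower, with 3.96% of mmu probes higher and 10.998% lower. The files do not say which prefixes belong to long non-coding RNA.

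**Figure D3:**
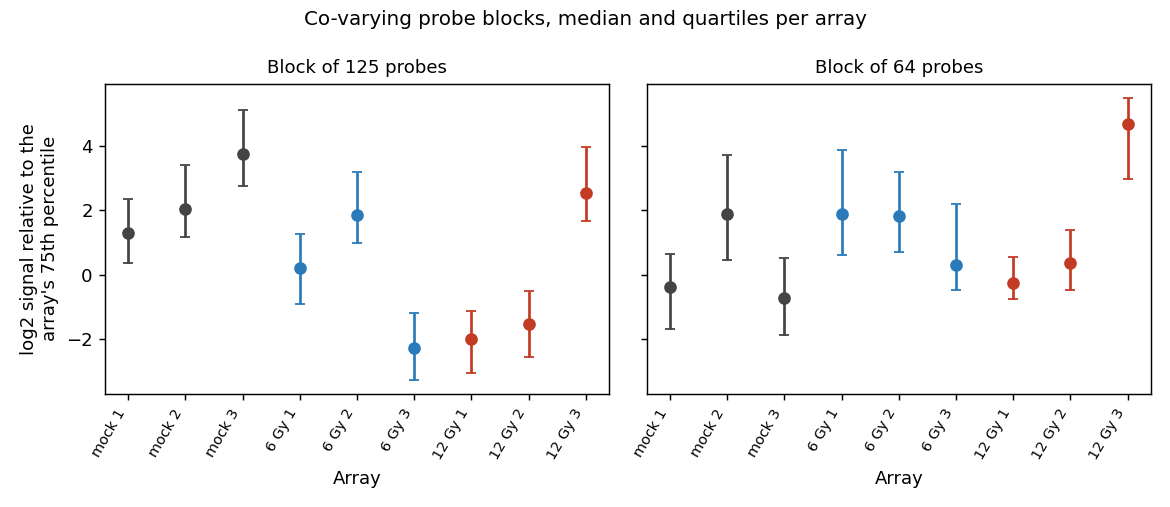
Median signal with quartiles of 2 blocks of co-varying probes on each array, as log2 relative to the array's 75th percentile, coloured by dose. The block of 125 probes has a median of -2.27 on 6 Gy replicate 3 and 2.52 on 12 Gy replicate 3, and the block of 64 probes is at 4.68 on 12 Gy replicate 3.

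Arrays of 1 dose were not always the most alike over the tested probes. 6 Gy replicate 3 correlated at 0.9813 and 0.9835 with 12 Gy replicates 1 and 2, which share its slide. With 6 Gy replicates 1 and 2 it correlated at 0.9652 and 0.9506. For 12 Gy replicate 3 the values were 0.960 and 0.9637 with 6 Gy replicates 1 and 2. With 12 Gy replicates 1 and 2, on its own slide, they were 0.941 and 0.953. Some probes differed widely between arrays of 1 dose. Of the tested probes, 249 spanned at least 4 log2 units across the 9 arrays, a set chosen after the values were seen. A block of 125 co-varying probes had medians of 1.29, 2.03 and 3.75 on the mock arrays, 0.19, 1.85 and -2.27 at 6 Gy, and -2.01, -1.54 and 2.52 at 12 Gy, for replicates 1, 2 and 3 of each group. A second block of 64 probes had its highest median, 4.68, on 12 Gy replicate 3.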

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

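Weights for array quality, listed before the data were examined, gave the counts farthest from those reported: limma then called 11650 probes over the 3 groups, 12274 for 12 Gy against mock, 5617 for 6 Gy against mock and 130 for 12 Gy against 6 Gy. These counts are not used as results. With the same weights 31 of 100 groupings of the arrays called probes, and 2 of 100 called at least 11650 over the 3 groups, the real one included in both counts and 11720 the highest other. In simulated data without group effects but with factors shared across probes, the weighted fit made calls in 14 of 20 runs and the unweighted fit in 2 of 20. With independent probes each fit did so in 2 of 20. These checks of the weights were chosen after their counts were seen.

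With only the arrays of the groups compared, limma called 1 probe for 12 Gy against mock and 0 for the other pairs. An unadjusted p under 0.05 with at least a 2-fold difference took 1106, 651 and 196 probes for 12 Gy against mock, 6 Gy against mock and 12 Gy against 6 Gy. Leaving out 1 array at a time gave 0 to 3 probes over the 3 groups, 0 to 2 for 12 Gy against mock, 0 to 1 for 6 Gy against mock and 0 to 2 for 12 Gy against 6 Gy. The calls came without mock replicate 1, mock replicate 3, 12 Gy replicate 2 or 12 Gy replicate 3. The correlation of the changes ran from 0.622, without 6 Gy replicate 3, to 0.849. A covariate chosen after seeing the data, the mean of the block of 64 variable probes, gave 3 probes for 6 Gy against mock. The cause of these differences was not tested. The other backgrounds, scalings, filters, slide blocks and the variance trend gave 0 adjusted calls in each comparison.

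With a replicate block limma called 0 probes in each comparison, and 5171 for 12 Gy against mock at an unadjusted p under 0.05. Samples with the same number deviated together at over 0.1 in 3 of 9 pairs, so the numbers were not taken as pairs. Scan followed slide and was not run separately, and the gene lists and long non-coding probes were not run.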

Other observations

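The tests in this part were chosen after the results were seen. Over the 3 groups, 100 of 100 groupings of the 9 arrays reached the adjusted count of 0, as any grouping must, so this count decides nothing about chance. The highest other grouping called 318 probes, where the highest over the same groupings was 2 in 10 simulations of independent probes with no structure. Those simulations held neither a dose effect nor correlated probes. In that grouping 1 group was all irradiated: 6 Gy replicate 3 with 12 Gy replicates 1 and 2, all on slide 3. The groupings with 121, 70 and 37 calls also held these arrays as 1 group. The contrast thus does not set a structure of the samples apart from dose or from correlation between probes. By the unadjusted count of 4571, 3 of 100 groupings gave as many, the real one included, and the highest other gave 5093. Those groupings ignored slide and were drawn from 280 possible ones. Every grouping and split of the arrays kept the probes that passed the filter by the real groups, which may favour the real grouping. Among the 24 groupings that exchanged arrays only within their slide, 5 gave as many, the real one included, with 8438 for the highest other. That grouping exchanged 6 Gy replicate 3 with 12 Gy replicate 3, and limma called 11 probes after adjustment, where the real one had 0. Other groupings among the 24 had up to 318 calls. Leaving out the real one, 3 of the 3 that kept the mock arrays together and 1 of the 20 that parted them gave as many. The 3 that kept the mock arrays together are too few for a share under 0.05, and the count covers all 3 groups. Exchanges within slides thus cannot decide whether the assignment of arrays to 6 or 12 Gy matters. The 20 that parted the mock arrays exchanged mock replicate 2, 3 or both with 6 Gy replicate 1, 2 or both. Most also exchanged 6 Gy replicate 3 with a 12 Gy array. The 1 of them that gave as many exchanged both pairs on slide 2, and 6 Gy replicate 3 with 12 Gy replicate 3. These 20 thus bear on mock against irradiated only in part.

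For pairs of groups, 10 splits are too few for a share under 0.05. The adjusted count of 0 was matched by 10 of 10 splits in each comparison, with highest other counts of 0, 2 and 0 for 12 Gy against mock, 6 Gy against mock and 12 Gy against 6 Gy. The unadjusted count was matched by 1 of 10 for 12 Gy against mock, 5660 against a highest other of 3587, and by 1 of 10 for 6 Gy against mock, 5158 against 3135. For 12 Gy against 6 Gy it was matched by 5 of 10, and the split that exchanged 6 Gy replicate 3 with 12 Gy replicate 3 gave 5199 against the real 1059.

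The block of 125 probes was near background on 6 Gy replicate 3 and on 12 Gy replicates 1 and 2, which share slide 3. Slide and scan may contribute, but medians within that slide spanned 4.79 log2 units. Dose may contribute too, yet 2 of 6 irradiated arrays, 6 Gy replicate 2 at 1.85 and 12 Gy replicate 3 at 2.52, were above the lowest mock median of 1.29. An exchange of labels between 6 Gy replicate 3 and 12 Gy replicate 3 was examined over probes unrelated to the block. Signals were taken as deviations from the mean of all irradiated arrays, whose correlations lean negative by construction. On these deviations 6 Gy replicate 3 correlated at -0.202 with the other 6 Gy arrays and 0.0641 with 12 Gy, which goes with an exchange. 12 Gy replicate 3 correlated at 0.0101 with 6 Gy and 0.0217 with the other 12 Gy arrays, which does not decide it. By limma's moderated F, the grouping with this exchange had 8438 probes at an unadjusted p under 0.05, against 4571 for the real one. It put the low arrays together, so any difference shared by them would raise that count too. These explanations cannot be told apart with 1 array on slide 3 that is not low, and a difference in the tissue sampled was not tested.

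Probes starting A_5 or A_6 lay higher after irradiation than probes starting mmu. A dependence on signal level would remove this within 5 equal bins of mean signal, where the lowest difference of medians was 0.130 on the log2 scale. Within 5 bins of GC content the lowest was 0.0901, in a bin with 38 mmu probes, so GC content may still contribute. The per-array difference was -0.12 ± 0.06 in mock, 0.09 ± 0.09 at 6 Gy and 0.06 ± 0.16 at 12 Gy (SD, n = 3). By exact two-sided permutation p was 0.1 at 6 Gy, the smallest that 3 against 3 arrays allow, and 0.2 at 12 Gy, and 0.3 for both after Benjamini-Hochberg over 6 tests, so the spread between arrays stays open.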
